A study of Mus musculus with 6 samples.

How the data were processed

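The series measured RNA of primary neural stem cells of the mouse that lack p53. The cells carried a retrovirus with either the control vector or PlagL2, the zinc finger transcription factor PLAGL2, and were kept in medium with 1% serum for 24 hours. Each of the 2 groups has 3 arrays, 6 in all, of a one-colour Affymetrix mouse design with 45101 probe sets. The labels number the arrays 1 to 3 in each group. They do not say whether the arrays of a group come from separate cultures, so the p-values measure the spread between these samples, part of which may be technical.

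The authors deposited 1 table of signal intensity values per probe set, on a linear scale. Per the submitters' processing notes the values were made with MAS5, the Affymetrix algorithm that weighs perfect-match against mismatch probes and scales each array to a common mean. The version of MAS5 is not given in the sources used here. In the table the 2% trimmed mean of each array was 100 to 100.001, so the arrays had been scaled to a target of 100, and no further normalization was applied. No detection calls were used here, so low signals have no stated limit of detection and folds against a low level depend on the constant added before the logarithm.

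The arrays had medians between 25.2 and 28.9. The ratios of the 3-prime to the 5-prime control probe sets were 1.30 to 1.77 for Actb and 0.894 to 1.14 for Gapdh, with the highest Actb ratio on PlagL2 array 2. The 3-prime probe set of the spiked cre control read 19160, 18290 and 13960 on vector arrays 1 to 3 and 13550, 14920 and 10380 on PlagL2 arrays 1 to 3, lower on PlagL2 arrays in each pair. The 3-prime control probe sets read 10460 to 12990 on vector and 7171 to 10200 on PlagL2 arrays for Actb, and 6894 to 7225 and 5203 to 6015 for Gapdh. With 3 arrays per group, the number of arrays limits the precision.

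Probe sets were named through the platform annotation supplied with the series. Of the 45101 probe sets, 64 were controls and were left out. Of the other 45037, 34945 had 1 gene symbol, 932 had several genes and gave no name, and 9160 were unlisted or had no symbol. A total of 34741 probe sets matched a gene identifier in the NCBI RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols needed an update. The RefSeq table served only for names and for which genes neighbour each other, because the build behind the probe annotation is not given in the sources used here.

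Values were analysed as log2(signal + 8), where 8 is the 25th percentile of all values rounded to a whole number. Fold changes are on this scale, which understates the change of low signals. The 40% of probe sets with the lowest mean on this log2 scale were left out. The limit, turned back to a signal, was 16.2. This kept 27023 probe sets, of which 22841 had 1 symbol. For each gene the kept probe set with the highest mean stood for the gene, which gave 12755 genes. PlagL2 arrays were compared with vector arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 4 residual and 3.58 prior degrees of freedom), two-sided, with the Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Intervals are 95% intervals of the moderated fit. An exact permutation test of 3 against 3 values cannot go below p = 0.1.

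Gene lists were tested with camera in limma with its preset correlation of 0.01 between genes, adjusted over the 19 lists. Beside it stand camera with an estimated correlation and fry. The lists were fixed before the data were examined. They cover Wnt ligands, Wnt receptors and co-receptors, beta-catenin target genes, Wnt antagonists, the Notch pathway, the BMP and TGF-beta response, neural stem and progenitor markers, markers of astrocytes, neurons and the oligodendrocyte lineage, cell cycle genes, serum immediate early genes, interferon response genes, unfolded protein and amino acid stress genes, p53 target genes, PLAG family and imprinted network genes, and markers of microglia and macrophages, endothelial cells, and fibroblasts and mural cells. Of their 359 entries, 12 had no probe set with that symbol alone. Members counted as changed over all genes and members counted after adjustment over the list alone are both given.

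The genes named in the text followed a rule, also fixed before the data were examined. It takes Plagl2, the 10 largest rises and the 10 largest falls among genes that passed the threshold with all 3 PlagL2 values on one side of all 3 vector values, Wnt6, Fzd2 and Fzd9, the markers Nes, Sox2, Gfap, Tubb3, Olig2 and Mki67, and the up to 4 members of each list with the smallest p. Wnt6, Fzd2 and Fzd9 were remembered from the study's paper as genes that respond to PLAGL2, and Wnt signaling is named in its title, so these genes and the Wnt lists are not independent evidence. Genes named outside the rule are said to be chosen after their values were seen.

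Whether the array numbers pair the groups was checked by correlating the deviations of same-numbered arrays from their group means over all genes tested. The correlations were 0.26, 0.33 and 0.48 for numbers 1, 2 and 3, each above the limit of 0.1 set beforehand, and each array correlated best with its own number in the other group. This cannot prove a pairing. The deviations within a group are tied to each other, and 3 arrays can be matched to 3 in only a few ways, so the best match may be by chance. The labels do not say what a number stands for, so any pairing comes from the data alone. The fit without the number as a block was the main one, as fixed beforehand, and the fit with the block (2 residual degrees of freedom) is given beside a result where it changes a call or a count over all genes tested.

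The steps were tested on simulated data with the gene means and the modelled variances of these arrays, 12755 genes, 200 of them changed, in 20 runs of the comparison of PlagL2 with vector. Without pair effects, 23.1% of genes with a 2-fold change, 80.2% with a 4-fold change and 98.2% with a 16-fold change were recovered, and 4.46% of the calls were false. With simulated pair effects the fit without the block recovered 2.76%, 50.1% and 88.4%, and the fit with the block recovered 6.42%, 64.9% and 94.5%. The pair effects had the same variance as the noise and were added to it. The spread in these runs was therefore larger than the modelled one, and their recoveries are not at the same spread as those without pair effects.

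The alternatives tried were a pseudocount of 1 and of 16, no filter and a filter of 60%, quantile normalization, median centring, no intensity trend, array weights, the replicate block, the mean of a gene's probe sets, leaving out probe sets whose names end in _x_at or _s_at (which can read several transcripts), probe sets instead of genes, each array left out in turn, and the other set tests. Leaving out both arrays numbered 3, and an estimated correlation together with the block, were added after seeing the data.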

Results

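Gene expression was measured in p53-null primary neural stem cells of the mouse, the self-renewing precursors of neurons and glia, after infection with a retrovirus carrying PlagL2 or the control vector. PLAGL2 is a zinc finger transcription factor of the PLAG family. Each group had 3 arrays, and 12755 genes were tested with limma on log2(signal + 8). The study, as its title states, concerns how PLAGL2 acts on Wnt signaling and differentiation, and the comparison of PlagL2 with vector asks which genes differ between the cells.

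The label of the groups was checked on Plagl2 itself. The probe set that stood for Plagl2 read 17.9 ± 3.7 in vector and 622 ± 296 in PlagL2 cells (SD, n = 3 each), a 22.9-fold difference (log2 fold change 4.51, SE 0.32, limma adjusted p = 0.0031), and all 3 PlagL2 values lay above all 3 vector values. The other Plagl2 probe sets did not pass. Of the other 2 kept probe sets, 1 read 45.8 in vector and 58.7 in PlagL2 cells and the other 28.8 and 22.4 (log2 0.31 and -0.27). A further probe set, below the filter, read 11.7 and 19.8. With the mean of the kept probe sets in place of the highest, the log2 fold change of Plagl2 was 1.52. Which parts of the transcript these probe sets read was not analysed here.

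Genes of imprinted loci were among the largest differences between the cells. Dlk1, an imprinted gene for a transmembrane protein of the Notch ligand family, rose from 30.5 ± 21.3 to 4449 ± 2116, a 124-fold difference (log2 6.95, SE 0.52, adjusted p = 0.0031). Meg3, the maternally expressed noncoding RNA of the same locus, rose 17.2-fold (log2 4.10, SE 0.20, adjusted p = 0.00028), and Igf2, the fetal insulin-like growth factor, rose 17.9-fold (log2 4.16, SE 0.62, adjusted p = 0.036). Mest, another paternally expressed gene, rose 4.63-fold (log2 2.21, SE 0.19, adjusted p = 0.0076). Of the 11 measured members of the list of PLAG family and imprinted network genes, 5 rose over all genes tested (Plagl2 itself among them), 0 fell and all 11 had a positive log2 fold change. Adjusted over the list alone 9 rose. Over all genes 3 rose without PlagL2 array 2 and 7 without vector array 3. The median log2 fold change was 2.21 (camera adjusted p = 5.7e-15, and adjusted p = 0.071 with an estimated correlation). These values include Plagl2, which the retrovirus carried, and the list was not tested without it. Without the filter 14 members were measured, with a median of 1.28, and 5 rose over all genes and 8 over the list alone. With the replicate block 7 members rose, among them Plagl1, a zinc finger gene of the same family (log2 1.67, adjusted p = 0.14, and 0.025 with the block), and Cdkn1c, an imprinted cell cycle inhibitor (log2 4.21, adjusted p = 0.083, and 0.012 with the block), both chosen after their values were seen. Both also passed with array weights and without vector array 3 (adjusted p = 0.0088 and 0.019), and without the probe sets whose names end in _x_at or _s_at Plagl1 was at -0.03 (adjusted p = 0.98).

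The probe sets of these genes did not all change by the same amount. The name of the probe set that stood for Dlk1 carries the suffix _s_at of probe sets that can read several transcripts. The other one read 2.96 in vector and 83.7 in PlagL2 cells and was higher on all 3 PlagL2 arrays. It did not pass the threshold (log2 2.54, limma adjusted p = 0.31 over all probe sets without the filter). Without the probe sets of that suffix Dlk1 therefore lost its call (adjusted p = 0.20). All 11 kept probe sets of Meg3 were higher in PlagL2 cells, by 1.51 to 5.71 on the log2 scale. Igf2 and Mest had 1 kept probe set each. Igf2 read 1577 on PlagL2 array 3 against 258 and 364 on the other PlagL2 arrays, and without array 3 its log2 fold change was 3.39 (adjusted p = 0.033). Its call was lost without the intensity trend (adjusted p = 0.060), without PlagL2 array 1 (0.073) or 2 (0.13), and without vector array 1 (0.087) or 2 (0.16).

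The differences around Dlk1 and Meg3 were looked at in the order of the genes on chromosome 12 of the mouse assembly GRCm38.p6, a set of genes chosen after the values of Dlk1 and Meg3 were seen. Inside the imprinted region 3 of 4 measured genes rose, Dlk1, Meg3 and the noncoding RNA Rian (log2 2.10, SE 0.27, adjusted p = 0.019). With 1 array left out Rian passed only without vector array 3, with adjusted p of 0.057 to 0.103 without the others. The noncoding RNA Mirg had a log2 fold change of 1.43 (adjusted p = 0.083, and 0.021 with the replicate block, 0.037 without vector array 3, 0.016 with array weights and 0.023 with the mean of probe sets). Of the 16 nearest measured genes outside, 8 on each side, 0 passed with limma, with log2 fold changes of -0.38 to 1.36, and 2, Cyp46a1 and Eml1, had an unadjusted p under 0.05. Cyp46a1 (log2 1.36, adjusted p = 0.15) passed with the replicate block (adjusted p = 0.012) and with array weights (0.037).

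**Figure D1:**
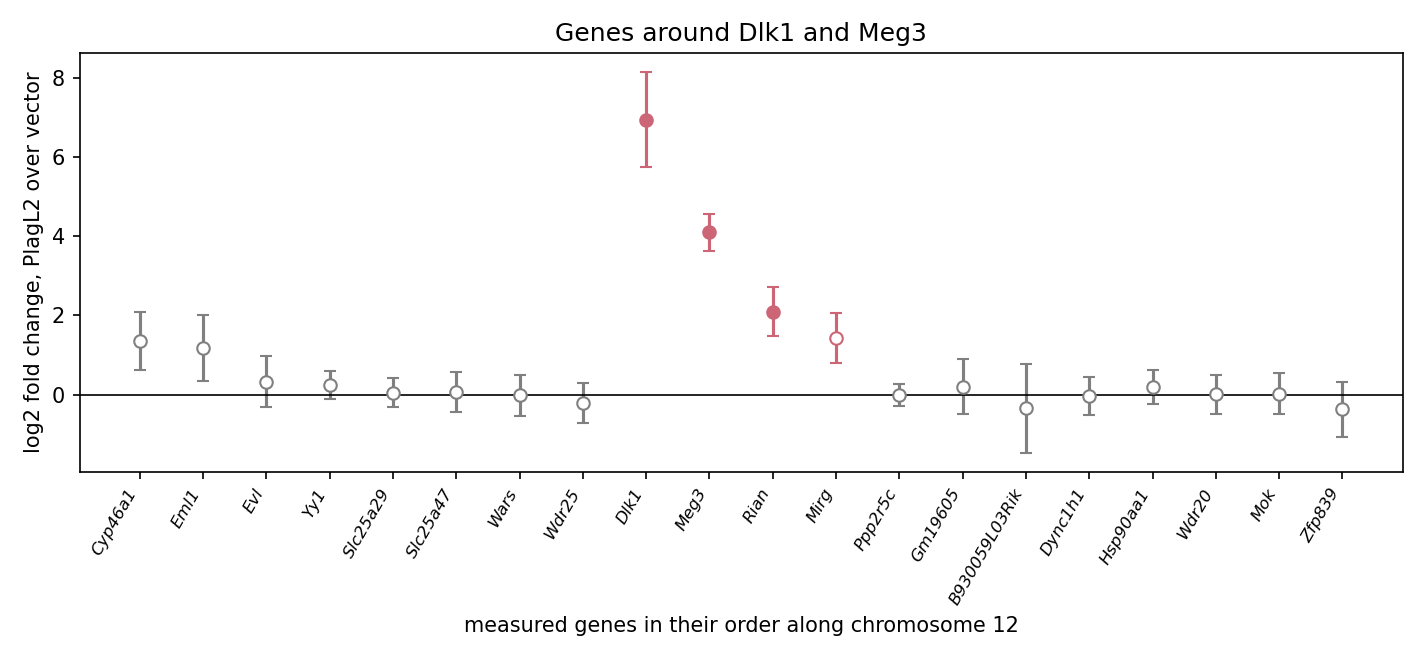
Log2 fold change of PlagL2 over vector (vertical axis, bars are 95% intervals, n = 3 arrays per group) for 20 measured genes in their order along chromosome 12. Red marks the 4 genes of the imprinted region and grey the 16 around it, filled circles passed the threshold, and Dlk1 at 6.95 and Meg3 at 4.10 lay highest.

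**Figure D2:**
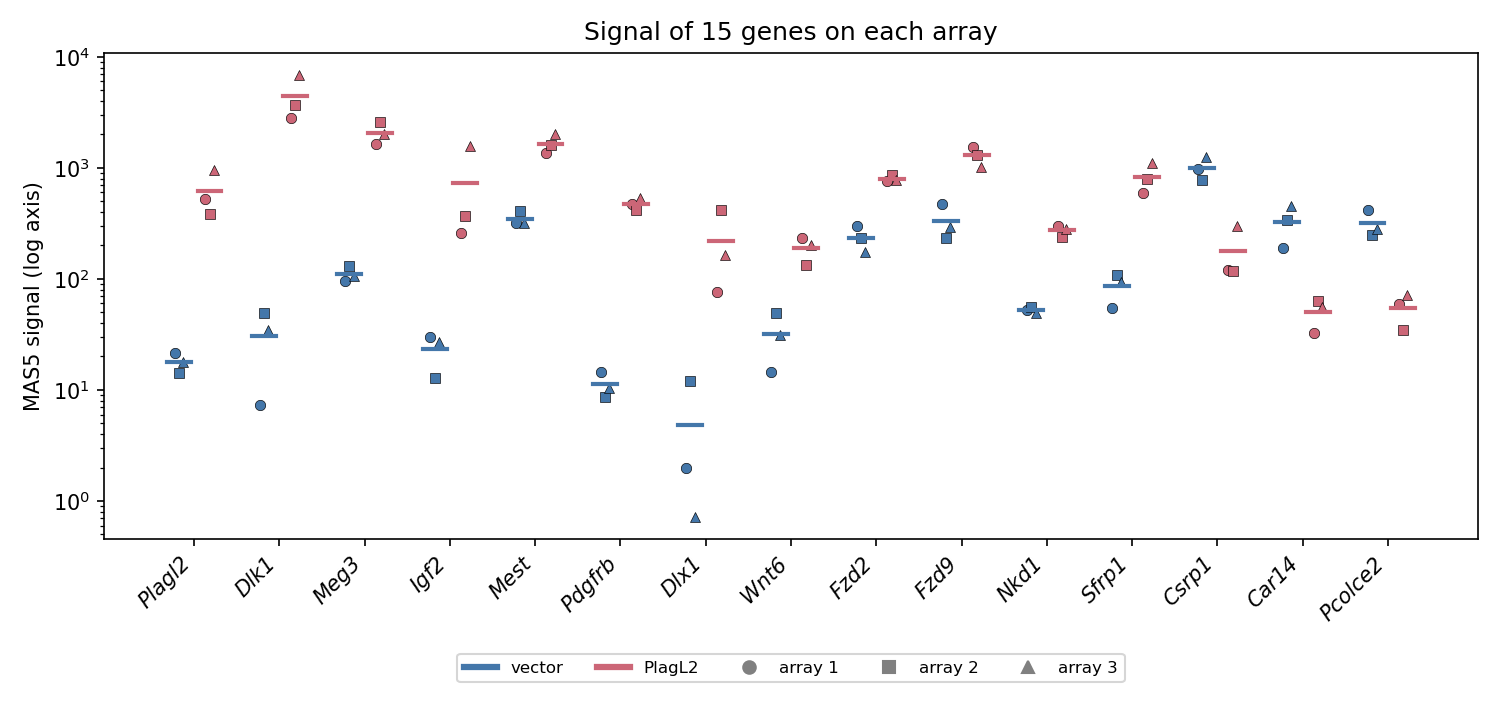
MAS5 signal (log axis) of selected genes on each of the 3 vector arrays (blue) and 3 PlagL2 arrays (red), with the array numbers as symbols and the group means as horizontal lines. The vector and PlagL2 points of each gene shown do not overlap, and Dlk1 went from a mean of 30.5 to 4449.

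In all, 72 genes rose and 21 fell, each by at least 1.5-fold, and for all 93 the 3 PlagL2 values lay on one side of the 3 vector values. Over all genes tested 18.4% had groups separated in this way, against 10% by chance if all 6 arrays were exchangeable. Pair effects, if present, would change that share. With the replicate block, 198 genes rose and 116 fell, and these 314 included all 93. Without vector array 1 the numbers were 53 and 13, without vector array 2 they were 14 and 0, and without vector array 3 they were 107 and 24. Without PlagL2 array 1, 2 or 3 they were 10 and 0, 6 and 0, and 11 and 1. Of the 27 named genes that passed, Dlk1, Pdgfrb, Plagl2, Meg3 and Nkd1 passed in all 6 of these fits, Mest and Sfrp1 in 5 (not without PlagL2 array 2, adjusted p = 0.088 and 0.097), and each of the others in 0 to 3. In those fits with 0 falls, 549, 559 and 501 genes were lower at an unadjusted p under 0.05 without vector array 2, PlagL2 array 1 and PlagL2 array 2.

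The largest rises after Dlk1 were Pdgfrb, the receptor of PDGF-BB and a marker of pericytes, from 11.2 ± 3.1 to 473 ± 61 (25.1-fold, log2 4.65, SE 0.20, adjusted p = 0.00016), then Plagl2, Igf2 and Meg3. They were followed by Dlx1, a homeobox gene of interneuron precursors (log2 3.93, SE 0.60), Kcne1l (log2 3.76), Gm11627 (log2 3.69), the tight junction gene Cldn9 (log2 3.46) and the secreted Wnt antagonist Sfrp1 (log2 3.16), with adjusted p between 0.010 and 0.037. This order depends on the pseudocount. With a pseudocount of 1 the log2 fold change was 5.43 for Dlx1 against 5.30 for Pdgfrb, and 4.59 for Cldn9 against 4.54 for Igf2. Without PlagL2 array 2 the log2 fold change of Dlx1 was 3.32 (adjusted p = 0.11), and without vector array 3 that of Gm11627 was 2.98 (adjusted p = 0.0047). Dlx1 read 4.88 ± 6.14 in vector cells, near the lowest signals, and lost its call without the filter (adjusted p = 0.054) and without the intensity trend (adjusted p = 0.060). Gm11627 lost its call with a pseudocount of 1 (adjusted p = 0.12), without the filter (adjusted p = 0.0503) and without the intensity trend (adjusted p = 0.060).

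The largest fall was that of Csrp1, a LIM domain protein of the cytoskeleton, from 1005 ± 241 to 180 ± 105 (log2 -2.54, SE 0.36, adjusted p = 0.028). The carbonic anhydrase Car14 (log2 -2.47), the collagen processing enhancer Pcolce2 (log2 -2.37), the neuropeptide neuromedin B, Nmb (log2 -1.82), the urea transporter Slc14a1 (log2 -1.63) and the monoglyceride lipase Mgll (log2 -1.61) came next. The potassium channel Kcna6 (log2 -1.60), Vwa1 (log2 -1.54), Ap1s2 (log2 -1.50) and the glycine transporter Slc6a9 (log2 -1.40) completed the 10 largest falls, with adjusted p between 0.016 and 0.037. Of these 10 genes, Csrp1, Car14, Mgll and Slc6a9 had adjusted p between 0.051 and 0.057 without the intensity trend, Csrp1 and Slc14a1 0.059 and 0.060 with the mean of their probe sets, and Vwa1 0.069 without the filter.

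The Wnt genes remembered from the study's paper were higher in PlagL2 cells. The ligand Wnt6 rose 5.21-fold from 31.7 ± 17.6 to 189 ± 51 (log2 2.38, SE 0.37, adjusted p = 0.039). The receptor Fzd9 rose 3.94-fold from 332 ± 123 to 1294 ± 264 (log2 1.98, SE 0.27, adjusted p = 0.024), and Fzd2 rose 3.40-fold from 234 ± 62 to 798 ± 52 (log2 1.77, SE 0.20, adjusted p = 0.016). The second probe set of Wnt6 differed by 1.71, the other 2 of Fzd2 by 2.05 and 1.70, and Fzd9 had 1 kept probe set. Wnt6 did not pass with a pseudocount of 1 (adjusted p = 0.056), without the filter (adjusted p = 0.061) or without the intensity trend (adjusted p = 0.062), and Fzd9 did not pass without the intensity trend (adjusted p = 0.053). With 1 array left out, Wnt6 passed only without vector array 3, and Fzd2 and Fzd9 only without vector array 1 or 3. The highest adjusted p values were then 0.18 for Wnt6 (without PlagL2 array 1), and 0.10 for Fzd2 and 0.15 for Fzd9 (both without PlagL2 array 2).

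Among 17 measured Wnt receptors and co-receptors 2 rose, Fzd2 and Fzd9, and 15 did not pass (camera upwards, adjusted p = 0.017, and adjusted p = 0.20 with an estimated correlation). Adjusted over the list alone 3 rose, and 5 rose and 1 fell without vector array 3. Fzd7 (log2 1.01) and Fzd6 (log2 1.43) did not pass, with adjusted p of 0.18 and 0.46, and passed with the replicate block (adjusted p = 0.043 and 0.038), where 4 receptors rose. The second kept probe set of Fzd6 did not rise (log2 -0.13). The receptor list did not pass without vector array 1 (adjusted p = 0.099), without PlagL2 array 3 (0.067), with array weights (0.061) or with the mean of probe sets (0.090). Of 10 measured Wnt ligands Wnt6 rose and 9 did not pass, among them Wnt7b (log2 1.08), Wnt5a (log2 0.84) and Wnt5b (log2 -0.59). As a list the ligands had a camera adjusted p of 0.053, and adjusted over the list alone 2 rose, or 1 without PlagL2 array 1 or 3 or vector array 1. Without vector array 3, 2 rose over all genes and 3 over the list alone. The ligand list passed without PlagL2 array 2 (adjusted p = 0.014) and without vector array 2 (0.041), and its adjusted p was 0.015 with the stricter filter, 0.049 with the pseudocount doubled and 0.047 after quantile normalization or median centring. Without the filter 19 ligands were measured, with a median log2 fold change of -0.12, 0 that rose over all genes and a camera adjusted p of 0.32. The list also did not pass with a pseudocount of 1 (0.059), without the intensity trend (0.066), with array weights (0.11) or with the replicate block (0.061). With an estimated correlation its adjusted p was 0.27.

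Targets of beta-catenin and antagonists of Wnt signaling also included genes that rose. Nkd1, which is both a target and an inhibitor of the pathway, rose 4.61-fold from 52.7 ± 3.3 to 273 ± 31 (log2 2.21, SE 0.16, adjusted p = 0.0031), with all 4 kept probe sets higher. The secreted antagonists Sfrp1 and Sfrp2 rose 8.92-fold and 6.93-fold (adjusted p = 0.010 and 0.016). Of 13 measured beta-catenin target genes 1 rose over all genes and 4 over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.18 with an estimated correlation). Over the list alone 2 rose without PlagL2 array 2 or 3 or vector array 1 or 2. The cyclin Ccnd1 (log2 1.94), Znrf3 (log2 0.61) and Tnfrsf19 (log2 1.25) had adjusted p of 0.11, 0.21 and 0.22, and Ccnd1 passed with the replicate block (adjusted p = 0.0031), which raised the count of targets that rose to 2. Ccnd1 also passed with the mean of its probe sets (adjusted p = 0.045) and with array weights (0.042). Over all probe sets without the filter its other kept probe sets passed (log2 2.46 and 1.79, limma adjusted p = 0.036 and 0.035), and the one that stood for it did not (0.17). Of 17 measured antagonists 3 rose over all genes, and 4 rose and 1 fell over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.18 with an estimated correlation). Without PlagL2 array 2, 1 antagonist rose over all genes. The Wnt lists, named after the study's title, are not independent evidence of direction.

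Markers of stem cells and of the neural lineages mostly did not pass. Nes (log2 0.86, adjusted p = 0.30) and Sox2 (log2 0.24, adjusted p = 0.66), both expressed in neural stem cells, the astrocyte protein Gfap (log2 -0.53, adjusted p = 0.50), the neuronal tubulin Tubb3 (log2 1.15, adjusted p = 0.30) and the oligodendrocyte lineage factor Olig2 (log2 0.61, adjusted p = 0.80) did not pass. Among 20 measured neural stem and progenitor markers the RNA-binding protein Msi1 rose 2.70-fold (log2 1.43, SE 0.16, adjusted p = 0.016) and 19 did not pass, while 3 rose and 1 fell over the list alone. Over all genes 2 rose without vector array 3 and 0 without vector array 2 or PlagL2 array 1, 2 or 3, and over the list alone 5 rose without PlagL2 array 1 or vector array 1 or 3. The list was shifted upwards (camera adjusted p = 0.0026, and adjusted p = 0.27 with an estimated correlation), and without vector array 3 it did not pass (adjusted p = 0.13). The cyclin Ccnd2 (log2 2.32, adjusted p = 0.092) and the nuclear receptor Nr2e1 (log2 0.95, adjusted p = 0.13) passed with the replicate block (adjusted p = 0.0031 and 0.030), which raised the count that rose to 3, and Sox9 (log2 -0.63, adjusted p = 0.13) did not. Ccnd2 also passed without vector array 3 (adjusted p = 0.029). All 7 kept probe sets of Ccnd2 were higher, and over all probe sets without the filter only the one at log2 2.59 passed (limma adjusted p = 0.043).

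Of 20 measured neuron markers Dlx1 rose and 19 did not pass, and over the list alone 3 rose and 1 fell. Dlx2, its partner in interneuron precursors, had a log2 fold change of 3.00 (adjusted p = 0.059, and 0.0051 with the replicate block, where 2 members rose), Elavl3 of 0.80 (adjusted p = 0.18) and Gap43 of -1.50 (adjusted p = 0.11). The list passed with a mean log2 fold change of 0.54 and a median of 0.04 (camera adjusted p = 0.038, and adjusted p = 0.40 with an estimated correlation). With 1 array left out the median ran from -0.02 (without PlagL2 array 2) to 0.42 (without vector array 2), and it was also below 0 without vector array 3. In those fits Dlx1 passed only without vector array 3. The neuron list did not pass without vector array 1 (adjusted p = 0.056) or 3 (0.18), without PlagL2 array 1 (0.063) or 2 (0.071), with a pseudocount of 1 (0.057), with array weights (0.20) or with the stricter filter (0.56).

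Of 19 measured astrocyte markers 0 passed over all genes with limma, 1 was higher and 4 were lower at an unadjusted p under 0.05, and 1 fell over the list alone (camera adjusted p = 0.35, and 0.026 downwards without vector array 1). With an estimated correlation, over all arrays, the camera adjusted p of the astrocyte list was 0.62. Over the list alone 4 fell without vector array 1, 4 rose and 3 fell without vector array 3, and 0 passed without PlagL2 array 1, 2 or 3. With the replicate block Atp1b2 (log2 -0.77, adjusted p = 0.043), Mlc1 (log2 -1.02, 0.048) and Sparcl1 (log2 -0.90, 0.018) were among 4 that fell, and the glutamate transporter Slc1a2 (log2 0.75, 0.043) was the 1 that rose. Without the block their adjusted p values were 0.11, 0.25, 0.35 and 0.22. The 17 measured oligodendrocyte lineage markers had a camera adjusted p of 0.105, and of 0.0057 upwards with the replicate block, with 0 members called by limma in either fit or over the list alone and 0 at an unadjusted p under 0.05. Camera with an estimated correlation gave an adjusted p of 0.62, and 0.39 together with the block. Their mean log2 level, relative to each gene's mean, was -1.49 on vector array 3 and -0.56 on PlagL2 array 3, against 0.07 to 0.71 on the other 4 arrays. The members with the smallest p were Opalin (log2 0.75), Enpp6 (log2 1.11), Myrf (log2 1.18) and Ugt8a (log2 1.21), with adjusted p between 0.44 and 0.69. With 1 array left out they ran from 0.56 to 1.00, 0.70 to 1.84, 0.40 to 2.17 and 0.0087 to 1.99. The list passed upwards without PlagL2 array 3 (adjusted p = 0.0010, with 1 member over the list alone) and without vector array 2 (0.0051), and pointed downwards without vector array 3 (0.63).

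All 24 measured cell cycle genes had a positive log2 fold change, with a median of 1.05, but 0 passed over all genes with limma and 12 were higher at an unadjusted p under 0.05. Adjusted over the list alone 5 rose, against 18 without PlagL2 array 1, 2 without vector array 2, and 0 without each of the other 4 arrays, without the intensity trend or with the mean of probe sets. Mcm4 (log2 1.19), Rrm2 (log2 2.27), Mcm2 (log2 1.44) and Mcm5 (log2 1.79) had adjusted p of 0.11 to 0.23, and the proliferation marker Mki67 (log2 1.96) had 0.38. Mcm4 was the 1 member that passed with the replicate block (adjusted p = 0.038). The list was shifted upwards (camera adjusted p = 6.0e-12, and adjusted p = 0.32 with an estimated correlation, which was 0.777). The mean difference of the list was 0.14 in pair 1, 0.76 in pair 2 and 2.59 in pair 3. Without PlagL2 array 3 the mean log2 fold change was 0.67, against 1.16 with it. On the same arrays numbered 3 the oligodendrocyte markers were low.

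Of 22 measured Notch pathway genes 0 passed with limma and 0 over the list alone, and 2 were higher at an unadjusted p under 0.05. Of these genes 1, Notch3 (log2 1.08, adjusted p = 0.14), passed with the replicate block (adjusted p = 0.032). Over the list alone 1 rose without vector array 2 or 3. Hey2 and Mfng (both log2 1.12) and Hey1 (log2 -0.52) did not pass, with adjusted p between 0.23 and 0.50. The list passed upwards (camera adjusted p = 0.032, and adjusted p = 0.43 with an estimated correlation), but not without vector array 3 (adjusted p = 0.57), without PlagL2 array 1 (0.14), with array weights (0.11), with the stricter filter (0.076) or with the mean of probe sets (0.053). On vector array 3 the mean log2 level of the Notch list was -0.73, against -0.01 to 0.28 on the others.

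Lists of stress and stimulus genes were lower in PlagL2 cells as lists, with 0 members that passed over all genes with limma. At an unadjusted p under 0.05, 4 serum genes, 6 interferon genes and 4 stress genes were lower and 1 stress gene was higher. Of 19 measured serum immediate early genes, which respond within minutes to growth factors, 17 had a negative log2 fold change, with a median of -0.84 and 0 calls over the list alone (camera adjusted p = 0.0030, and adjusted p = 0.38 with an estimated correlation). Over the list alone 10 fell without vector array 3, 5 with array weights and 6 with the replicate block, and the median was -0.57 without vector array 1 and -0.52 without vector array 2. Ier3 (log2 -0.90), Egr2 (log2 -1.21), Jun (log2 -1.01) and Junb (log2 -1.46) had adjusted p of 0.19 to 0.40, and Ier3 had 0.049986 with the replicate block. The list did not pass without vector array 2 (adjusted p = 0.11). All 13 measured interferon response genes had a negative log2 fold change, with a median of -0.57, and 2 fell over the list alone (camera adjusted p = 3.0e-05, and adjusted p = 0.18 with an estimated correlation). Without PlagL2 array 3 that count was 4, without vector array 1 it was 1, and without each of the other 4 arrays it was 0. Ddx58 (log2 -0.76), Xaf1 (log2 -1.04), Usp18 (log2 -0.94) and Ifit3 (log2 -1.17) had adjusted p of 0.21 to 0.37, and Ifit3 fell with the replicate block (adjusted p = 0.035). Of 15 measured unfolded protein and amino acid stress genes 14 had a negative log2 fold change, with 0 calls over the list alone (camera adjusted p = 0.0041, and adjusted p = 0.32 with an estimated correlation). Pdia4 (log2 -0.51), Ppp1r15a (log2 -0.47) and Asns (log2 -0.73) were lower on average and Hsp90b1 (log2 0.40) was higher, with adjusted p of 0.23 to 0.35. This list did not pass without vector array 3 (adjusted p = 0.12) or with the mean of probe sets (0.061).

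**Figure D3:**
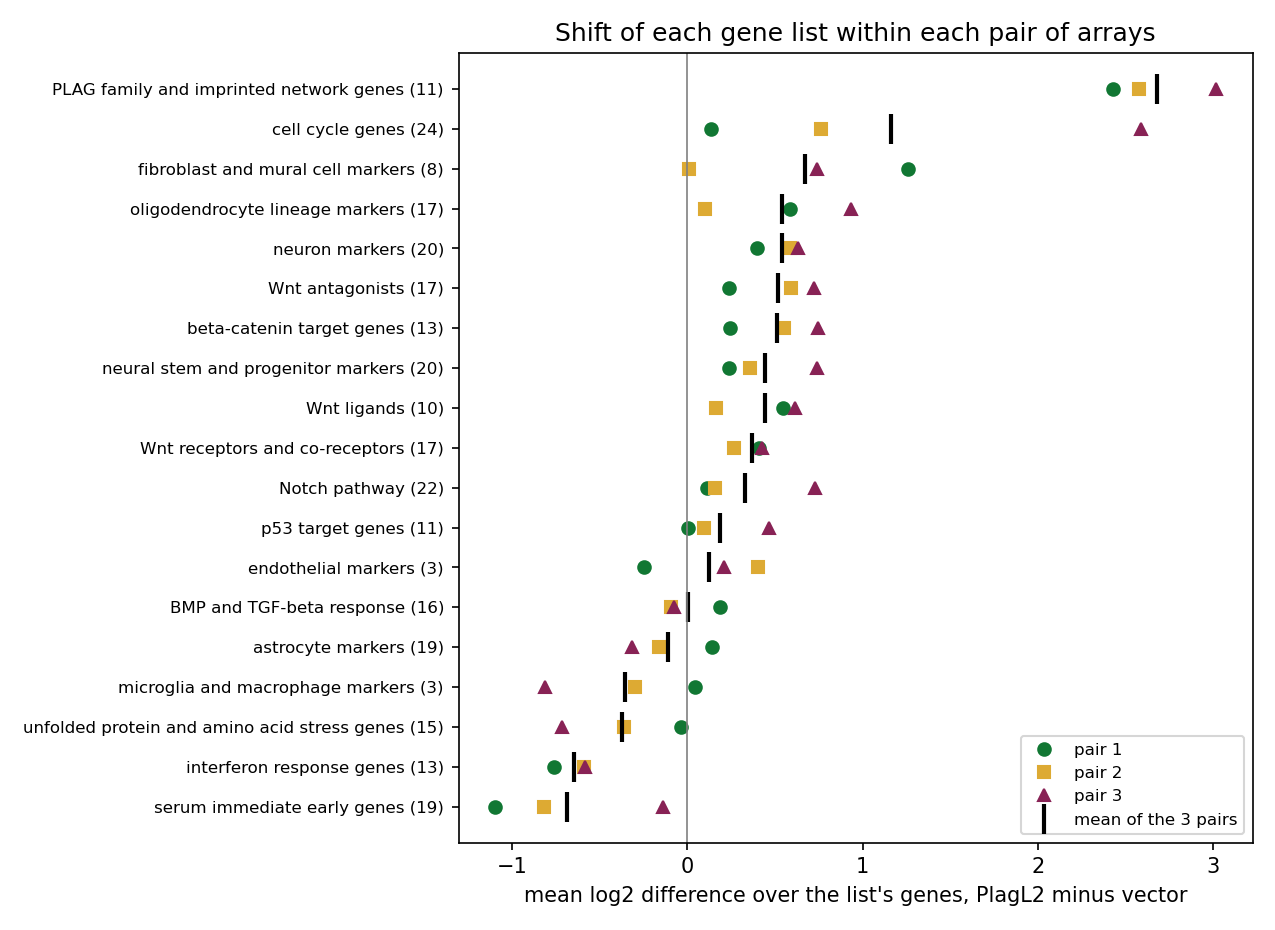
Mean log2 difference between PlagL2 and vector over the measured genes of each list, with the number of genes in parentheses, for each pair of same-numbered arrays (circle, square and triangle) and their mean (bar). The cell cycle list lay at 0.14, 0.76 and 2.59 in pairs 1, 2 and 3, and the PLAG family and imprinted list, which includes Plagl2, between 2.43 and 3.02.

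Other lists did not pass. The p53 target genes, measured in cells without p53, had a camera adjusted p of 0.34, with 0 of 11 called by limma over all genes, and 1 (Cdkn1a) over the list alone and at an unadjusted p under 0.05. With 1 array left out the list-alone count was 1 only without vector array 1. The cell cycle inhibitor Cdkn1a had a log2 fold change of 1.68 (adjusted p = 0.18). Its second probe set passed over all probe sets without the filter (log2 2.90, limma adjusted p = 0.020). Cdkn1a passed with the mean of its probe sets (log2 2.29, adjusted p = 0.023), with array weights (0.028) and without vector array 1 (0.031). The log2 fold change was 0.88 for Bbc3, 0.84 for Trp53inp1 and -1.35 for Fas (adjusted p = 0.53 to 0.55), and with 1 array left out it ran from 0.33 to 1.24, 0.31 to 1.26 and -1.98 to -0.54. The 16 measured genes of the BMP and TGF-beta response had an adjusted p of 0.78, with Id4 at log2 0.59, Id1 at -0.60, Tgif1 at -0.47 and Grem1 at -0.48. Markers of cells that a primary culture could also hold were few above the filter. The 3 measured markers of microglia and macrophages (Cd14 at log2 -0.73, Csf1r at -0.33 and Cd68 at -0.00) had an adjusted p of 0.35, and the 3 of endothelial cells (Kdr at -0.55, Flt1 at 0.66 and Esam at 0.26) had 0.77. In these 3 lists limma called 0 members over all genes or over the list alone (1 microglia and 1 endothelial marker fell over the list alone without vector array 1), and 1 BMP gene was higher and 1 lower at an unadjusted p under 0.05.

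Of 8 measured fibroblast and mural cell markers, Pdgfrb rose and 7 did not pass, and 2 rose over the list alone (camera adjusted p = 0.11) and with the replicate block. Here the median log2 fold change was -0.24, whereas the mean was 0.67 and the test pointed upwards. The median was 0.23 without PlagL2 array 2 and 0.17 without vector array 3. Des, of muscle and pericyte filaments, had a log2 fold change of 2.29 (adjusted p = 0.083, and 0.048 with the replicate block), the collagen gene Col1a1 of 0.50 (adjusted p = 0.66) and the proteoglycan Cspg4 of -0.30 (adjusted p = 0.72). The second probe set of Des did not rise (log2 -0.34). The list passed without PlagL2 array 2 (camera adjusted p = 0.022). With an estimated correlation, over all arrays, its camera adjusted p was 0.40.

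By camera with the preset correlation, 11 of the 19 lists passed, 8 upwards and 3 downwards, and 12 passed with the replicate block. Some lists share genes, so these are not separate findings. As fixed, the beta-catenin target and the antagonist list share Nkd1, Nkd2, Znrf3, Rnf43, Axin2, Dkk1, Wif1, Apcdd1 and Notum, whether or not each was measured. Notch1, Hes1 and Hes5 are in both the Notch and the neural stem list. Further pairs of lists share genes too, among them Olig2, Lgr5 and Myc. With an estimated correlation 0 of 19 passed, and in that test 4 lists had an unadjusted p under 0.05 (7 by fry). By fry, which tests whether the genes of a list move on balance one way, 1 list passed, that of PLAG family and imprinted genes (adjusted p = 0.0038). That list includes Plagl2, which the retrovirus carried, and was not tested without it. Without vector array 3 the number of lists that passed was 7.

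The arrays were similar to each other. Over the 12755 genes the Pearson correlation across genes, which are not independent replicates, was 0.950 to 0.967 between PlagL2 arrays, 0.900 to 0.951 between vector arrays and 0.893 to 0.948 between the groups. The mean correlation within groups exceeded that between groups by 0.018, and by 0.0079 (without PlagL2 array 2) to 0.027 (without vector array 1) with 1 array left out. Of the variance, 36.7% lay on a first principal component on which vector array 3 stood at 58 and the others between -26.9 and 3.71. On the second component, with 31% of the variance, the vector arrays lay at 0.46 to 39.6 and the PlagL2 arrays at -38.9 to -8.71. Without both arrays numbered 3, chosen after seeing the data, 93 genes rose and 35 fell and 8 lists passed.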

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

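The test of other imprinted genes was set before its result was seen, and quantile normalization, median centring, the fits without 1 array and camera with an estimated correlation were planned before the data were examined. The comparisons with Nnat, of probe sets, of collagen genes, of spiked controls, of pairs and of the median over all genes were chosen after the results they concern had been seen. So were the use of the scalings to weigh the cell cycle list and the counts over splits. The tests of imprinted probe sets, collagen genes and scaling were also changed after their first results. On kept probe sets alone the collagen test had argued against such cells, the first scaling test had argued against scaling, and the probe set test, before it needed 3 other probe sets per gene, had argued against other transcripts for Dlk1 and Mirg too.

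Probe sets without a single gene symbol were not part of the comparison of genes, and 6 of the 4182 tested were higher in PlagL2 cells, with 1 lower. They came up as a signal in data that the comparison did not use. The largest was probe set 1448194_a_at, from a mean of 74.5 to 5879 (82.3-fold, limma adjusted p = 0.0042 over the 27023 kept probe sets). It was followed by 1431094_at (10.2-fold), 1447352_at (9.83-fold), 1428525_at (4.98-fold), 1450042_at (3.54-fold) and 1437086_at (2.20-fold). The lower one was 1415951_at, with a log2 fold change of -1.32.

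The higher signals of imprinted genes were weighed first. If imprinted genes changed as a class, other imprinted genes would be higher too, but 25 measured ones had a median log2 fold change of 0.04 (95% bootstrap interval -0.18 to 0.15, 13 higher and 12 lower) and a camera p of 0.98, or 0.981 with an estimated correlation. These leave out the imprinted genes of the lists, the region's Rian and Mirg, and Nnat (log2 0.98, adjusted p = 0.66), whose values had been seen: with Nnat camera p was 0.876, and over all 38 measured imprinted genes 26 were higher (5 passed) and 12 lower, with a median of 0.15. Probe sets that read other transcripts are argued against for Meg3 and Rian, since without the filter 13 of their 13 other probe sets were higher on all PlagL2 arrays, against 6.33% of all probe sets. They stay open for Dlk1, Mirg and Igf2, whose other probe sets, 1 for each and 3 in all, were higher but too few, and for Mest, which has 0 others. Fibroblasts or mural cells in the PlagL2 cultures would bring collagen transcripts and stay open: the brightest probe sets of Col1a1 and Col1a2 read 21.6 and 46.9 in vector and 31.4 and 40.4 in PlagL2 cells, but a dimmer one of each had log2 fold changes of 1.19 and 0.98 and was higher on all PlagL2 arrays, the highest upper 95% bound was 2.46 against lower bounds of 4.18 and 2.37 for the Pdgfrb probe sets, and Des (log2 2.29, adjusted p = 0.048 with the replicate block) goes with such cells, though its second probe set did not rise (log2 -0.34) and 5 of the 8 measured markers of these cells were lower, with a median of -0.24. An effect of PLAGL2 on these genes also stays open.

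The higher cell cycle list was weighed next. The mean shift of the list was 1.17 after quantile normalization and 1.15 after median centring. This decided nothing about scaling, since the arrays had been scaled already and quantile normalization moved the values by a median of 0.0153 on the log2 scale. A factor per array would move all genes about alike. The median difference over all genes tested was -0.020, and -0.039, -0.023 and -0.0047 in pairs 1, 2 and 3. The list lay at 0.14, 0.76 and 2.59 in these pairs. By construction such a factor cannot shift a list relative to other genes. The scaling to a common mean had also brought the arrays to 1 level before the median over all genes was taken. These values therefore decide nothing about scaling. A shift of all genes together, or a scaling that differs by signal level, stays open. The 18 probe sets of spiked controls were all lower on average on PlagL2 arrays, by a mean log2 of 0.329 (95% interval of the difference -1.01 to 0.348), and lower in each pair, against the direction of a scaling that raised PlagL2 values, but the sources used here do not give the amounts added. The arrays numbered 3 carried more of the shift: over pairs 1 and 2 its mean was 0.448, against 1.16 over all pairs. The list still passed camera in each fit that left out 1 array, and not with an estimated correlation (adjusted p = 0.325). An effect of PLAGL2 on the cell cycle stays open.

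That 1 of the Plagl2 probe sets rose and the others did not was weighed last. A retroviral transcript without the sequence that the other probe sets read could give this, and the median log2 fold change of the other probe sets was 0.313. The positions of the probe sets in the transcript were not used here, which keeps this open.

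The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 93 genes and the highest other split 2, so 1 of the 10 gave as many. For gene lists the real split gave 11 and the highest other 8, and again 1 of the 10 gave as many. The 3 other splits that part all pairs gave 0 genes each by limma (125, 110 and 303 at an unadjusted p under 0.05, against 1486 in the real split) and 4, 2 and 6 lists. Every split but the real one has vector and PlagL2 arrays on both sides. Any group difference then adds to the spread within its sides and lowers its counts, so part of this contrast was set in advance. The split with 8 lists set vector and PlagL2 array 1 with PlagL2 array 3 against the others.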

How the results depend on the processing

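The settings with both arrays numbered 3 left out, and with an estimated correlation together with the block, were chosen after seeing the data. Of 321 values of the 27 called named genes under other settings, 301 stayed past the threshold and 20 did not, with 0 reversed, and with 1 array left out 74 of 162 did. In all 6 of those fits Plagl2, Dlk1, Meg3, Pdgfrb and Nkd1 passed, with Plagl2 at 4.16 to 4.81. Of named genes not called, Cdkn1a, Ccnd1, Ccnd2, Dlx2, Fzd7, Tubb3, Sox9, Gap43, Ddx58, Xaf1, Atp1b2, Ier3 and Egr2 passed with array weights, Enpp6, Ccnd2 and Dlx2 without both arrays numbered 3 (adjusted p = 0.038, 0.040 and 0.046), where Dlx1 (3.75, 0.066) and Wnt6 did not, and Wnt5a without vector array 3 (0.046). With the replicate block, calls over the list alone numbered 3 higher and 1 lower for Wnt ligands, 4 higher for receptors, 5 for beta-catenin targets, 5 (1 lower) for antagonists, 3 for Notch, 1 for BMP, 6 (1 lower) for neural stem, 2 (6 lower) for astrocyte, 7 (1 lower) for neuron and 8 for cell cycle genes, and 4 interferon and 1 stress gene lower. With 1 array left out the log2 fold change moved by over 1.5 times for 28 of the 65 named genes not called and for 0 of the 27 called. The cause of the changes below was not tested, except that fits without an array have fewer samples. Low signals near the background limit what the arrays can show, and groups of 3 were not tested for outlying arrays.

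Genes that rose numbered 195 with array weights, 198 with the block and 6 to 107 with 1 array left out. Genes that fell numbered 7 without the intensity trend, 110 with array weights, 116 with the block, 35 without both arrays numbered 3 and 0 to 24 with 1 array left out. The gene lists that passed numbered 0 with an estimated correlation, 0 with it and the block, 1 by fry and 7 to 12 with 1 array left out (7 without vector array 3).

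Wnt6 did not pass with a pseudocount of 1 (2.66), without the filter or the trend (2.38 each) or without both arrays numbered 3 (2.36), with adjusted p of 0.056 to 0.071 in these 4 settings and down to 0.023 in the others, and lay at 2.02 to 2.70 with 1 array left out. Fzd9 did not pass without the trend (1.98, adjusted p over settings 0.0042 to 0.053) and lay at 1.76 to 2.25, and Fzd2 at 1.67 to 1.95, with 1 array left out.

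Among the genes named by the rule, and among the lists by the direction of camera, changes of sign came in those that did not pass. Mycn, chosen after its values were seen, fell (log2 -1.11, limma adjusted p = 0.039) but was at 0.56 with the mean of probe sets. Mycn also did not pass without the filter (0.1), after quantile normalization (0.15) or without the intensity trend (0.064), and passed in the other settings tried on genes. With 1 array left out Mycn passed only without vector array 3 (0.072 to 0.24 without the others). Cd68 was at 0.00021 with the pseudocount doubled, 0.0747 after quantile normalization, 0.0149 with array weights, 0.23 without both arrays numbered 3 and -0.14 to 0.13 with 1 array left out. Flt1 was at -0.0229 with the mean of probe sets and -0.33 to 1.20 with 1 array left out, Esam at -0.11 to 0.48, and Olig2 at -0.35 to 1.14, or -0.12 without both arrays numbered 3. The BMP and TGF-beta list turned with adjusted p of 0.70 without the filter, 0.929 with array weights and 0.889 with the mean of probe sets (0.612 to 0.916 with 1 array left out), the microglia list with 0.979 and the endothelial list with 0.206 without the filter, and the endothelial list with 0.889 with the mean of probe sets (0.66 to 0.948 with 1 array left out). The oligodendrocyte list had 0.0010 to 0.626 with 1 array left out, and the astrocyte list turned with 0.975 without both arrays numbered 3, where the Notch, neural stem, neuron and stress lists did not pass (0.132, 0.0507, 0.0783 and 0.0783) and the oligodendrocyte list did (0.030).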

Other observations

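Genes outside the lists, chosen here after their values were seen, also differed between the cells. Maged2, of the melanoma antigen family, rose 8.21-fold from 187 ± 4.9 to 1594 ± 139 (SD, n = 3 each, log2 3.04, SE 0.13, limma adjusted p = 0.00016). The long noncoding RNA Miat rose 4.87-fold (adjusted p = 0.016), and the cyclin Ccnd3 rose 3.34-fold from 431 ± 92 to 1473 ± 418 (adjusted p = 0.025). With the mean of probe sets the log2 fold change of Maged2 was 1.80 (adjusted p = 0.0058), and Miat and Ccnd3 did not pass (adjusted p = 0.055 and 0.25), nor did Ccnd3 without the intensity trend (0.056). Maged2 passed in each fit that left out 1 array. Miat did not pass without PlagL2 array 1 (0.082) or 2 (0.10) or vector array 2 (0.054), and Ccnd3 passed only without vector array 3 (0.058 to 0.105 without the others).

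The growth factor Tgfb2 fell from 509 ± 93 to 188 ± 12 (log2 -1.38, adjusted p = 0.018), but did not pass without PlagL2 array 1 (0.082), 2 (0.12) or 3 (0.088) or vector array 2 (0.090). For all of these genes the PlagL2 values lay on one side of the vector values.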
